A study of Mus musculus with 8 samples.

How the data were processed

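RNA was measured in 8 libraries of mouse macrophages that lack endogenous Sting, 2 for each of 4 transgene labels. Cells were seeded at 4 M per 10 cm dish, stimulated with 500 µg/ml CMA for 4 h. RNA was extracted with phenol-chloroform, and the polyadenylated part was turned into single-end Illumina libraries, per the labels' protocols. The groups were taken from the transgene label of each sample and the replicate numbers from the sample titles. Nothing in the labels says that the 2 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

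The deposited table holds RPKM, reads per kilobase of gene model scaled to the size of the library, computed by the authors for 53715 genes. Cutadapt 1.16, HISAT2 2.1.0 and the mouse builds GRCm38 and mm10 are named per the submitters' processing notes, without their roles. The tool that counted reads, the annotation release and the strand setting are not given in the sources used here. Without a strand setting, reads of genes that share exonic sequence cannot be told apart, which makes the values of these genes uncertain: Cxcl10 (with Art3), Irf7 (Phrf1), Irf9 (Rnf31), Rtp4 (Gm45338), Oasl1 (Gm13822), Cebpa (Gm45091), Gapdh (Iffo1), C5ar2 (Gm26473), mt-Atp8 (mt-Atp6), Cd74 (Mir5107), Trex1 (Atrip), Irf1 (Gm17334) and Csrnp1 (1700019L13Rik). Members of gene families with near-identical sequence, such as the Ifit and Oas genes, are uncertain in the same way. Gene symbols were found for 53620 identifiers and 95 were left under their identifiers. Coordinates, exon lengths and GC content were taken from the GENCODE annotation of GRCm38.

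RPKM are not counts, so no count model served for the results. Depth was read from the steps of the values: RPKM times exon length came out as whole multiples of 1 step per library, within 0.05 of a read, for 95.0% to 95.6% of nonzero values. The depths were 20.1 to 171 M reads. A value of 0 was read as fewer than 3 reads, and a fold against a group at 0 in both libraries is given as at least the ratio to the mean RPKM that 3 reads would have in that group; such floors cover counting error only. Between the 2 libraries of a group, 72.3% to 78.0% of genes with at least 100 reads differed beyond counting error. The 2 were therefore not copies of 1 set of reads, though they could still be 2 preparations of 1 RNA. Libraries of different groups were not compared in this way.

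Tests were run with limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), for the 13475 genes with an RPKM of at least 1 in at least 2 of the 8 libraries. That filter keeps a gene that reaches 1 in the 2 zfCTT libraries alone, such as Il12b. In every comparison with zfCTT, counts and medians over the tested members of a list can therefore lean towards zfCTT. All 8 libraries entered 1 fit with a mean per group, which leaves 4 residual degrees of freedom, and each of 6 contrasts had a moderated two-sided test with an intensity trend. Benjamini-Hochberg adjustment was applied within a contrast at 0.05. Fold changes are on the log2(RPKM + 1) scale, which understates the change of genes with low values. Errors beside levels are SD over 2 libraries and errors beside log2 fold changes are SE from the fit. Each named gene said to have risen or fallen over all genes had both libraries of 1 group above both of the other.

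Gene lists, 30 in all, were fixed with the groups, the tests and the first set of other settings before the data were examined. The 24 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over lists within a contrast. Camera with an estimated correlation and fry, a rotation test that does not compare a list with other genes, were run beside it. The genes named were set by rule: in each comparison up to 8 of the largest rises and 8 of the largest falls past the threshold whose libraries do not overlap between the groups. Unnamed gene models, pseudogene symbols and genes with a mean RPKM under 1 were left out of these. To them were added up to 3 members of each response list with the smallest adjusted p, and 20 fixed genes, among them Tmem173, Ifnb1, Cxcl10, Tnf, Nfkbia, Actb and Gapdh.

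The method was tested on simulated libraries built from the mean RPKM, depths and residual spread of all 8 libraries, with changes placed in zfCTT. Of 13118 genes tested against no_transgene, 50 were changed at each fold size, drawn from genes with a mean RPKM of at least 5. Noise was independent between libraries, without a replicate effect or GC trend. The recovery therefore need not hold for genes with lower values or for the real libraries. The method recovered 10% of genes changed 2-fold, 58% at 4-fold, 86% at 8-fold and 84% at 16-fold, with 0 calls in the wrong direction. In this simulation 2 unchanged genes were called, 1.65% of the calls.

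Settings fixed in advance for comparison were pseudocounts of 0.1 and 0.5, no filter on low values, a mean RPKM of at least 5, median-of-ratios scaling, quantile normalization, a fit on the 4 libraries compared, library weights, a robust prior, the replicate number as a block, a minimum log2 fold change of 1, and leaving out each library in turn. With 1 library of a group left out, the other is assumed to vary like the remaining groups. Added after seeing the data were limma voom on the recovered reads, a fit without no_transgene replicate 1 and dCTT replicate 1, protein-coding genes alone with the RPKM rescaled, and removal of each library's GC trend by loess. Il6, Il1b and Cxcl1 were among the fixed genes but fell under the filter and have no test.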

Results

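Poly(A) RNA-seq was read from 8 libraries of mouse macrophages that lack endogenous Sting and stably express either no STING transgene or 1 of 3 STING proteins. All cells had been treated for 4 h with 500 µg/ml CMA (10-carboxymethyl-9-acridanone), a small molecule that binds and activates mouse STING, so no library shows unstimulated cells. The 4 groups, with 2 libraries each, are named here no_transgene, mSTING, dCTT and zfCTT after the transgene labels; CTT is the C-terminal tail of STING, the part that recruits signalling proteins. The title of the series places the question in the tail's share in interferon and NF-κB signalling. Recovered depth was 27.7 and 101 M reads for no_transgene, 88.1 and 88.2 for mSTING, 55.7 and 171 for dCTT, and 20.1 and 34.8 for zfCTT. The deepest library had 8.55 times the reads of the shallowest. Of the 53715 genes in the table, 13475 reached an RPKM of 1 in at least 2 libraries and were tested. Across those genes, the log2 values of the 2 libraries correlated at r = 0.946 for no_transgene, 0.977 for mSTING, 0.974 for dCTT and 0.965 for zfCTT. Genes are not independent replicates. On the first principal component, which held 38.2% of the variance, zfCTT replicate 1 scored 65.4 and zfCTT replicate 2 scored 19.3. The other 6 libraries ran from 1.29 down to −29.7. No_transgene replicate 1 and dCTT replicate 1 stood apart from the rest on the second component, which held 37.0%, with scores of 59.7 and 30.7 against 0.949 or less in the other 6 libraries.

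Tmem173 (ENSMUSG00000024349, GRCm38 chromosome 18, 35733679 to 35740554, minus strand), the gene that encodes STING and was knocked out in these cells, read 3.23 and 2.42 RPKM without transgene, 10.6 and 22.2 with mSTING, 22.7 and 15.0 with dCTT and 14.2 and 20.6 with zfCTT. Every library with a transgene thus lay above both libraries without one, in the order the labels call for, although reads of the transgene and of any transcript left from the disrupted locus cannot be separated in a gene total. The log2 fold change of Tmem173 over no_transgene was 2.11 ± 0.38 (SE, n = 2 per group) for mSTING, 2.36 ± 0.38 for dCTT and 2.25 ± 0.38 for zfCTT. None passed the limma test over all genes, with adjusted p of 0.684, 1 and 0.0539. Within the list of STING and nucleic acid sensing genes, 18 of which were tested, Tmem173 rose in each of the 3 when adjusted over the list alone, at adjusted p = 0.00959, 0.0102 and 0.00660. The zfCTT value was past the threshold over all genes in the fits without mSTING replicate 1 (adjusted p = 0.0404) or 2 (0.0403) and with the replicate number as a block (0.0452). It was also past it among protein-coding genes alone (2.31, adjusted p = 0.0144) and with the GC trend removed (2.25, adjusted p = 0.0465), 2 settings chosen after seeing the data. Between the transgenes, Tmem173 in zfCTT differed from mSTING by 0.14 ± 0.38 and dCTT from mSTING by 0.25 ± 0.38. Both changed sign without mSTING replicate 1, at −0.35 and −0.25.

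**Figure D1:**
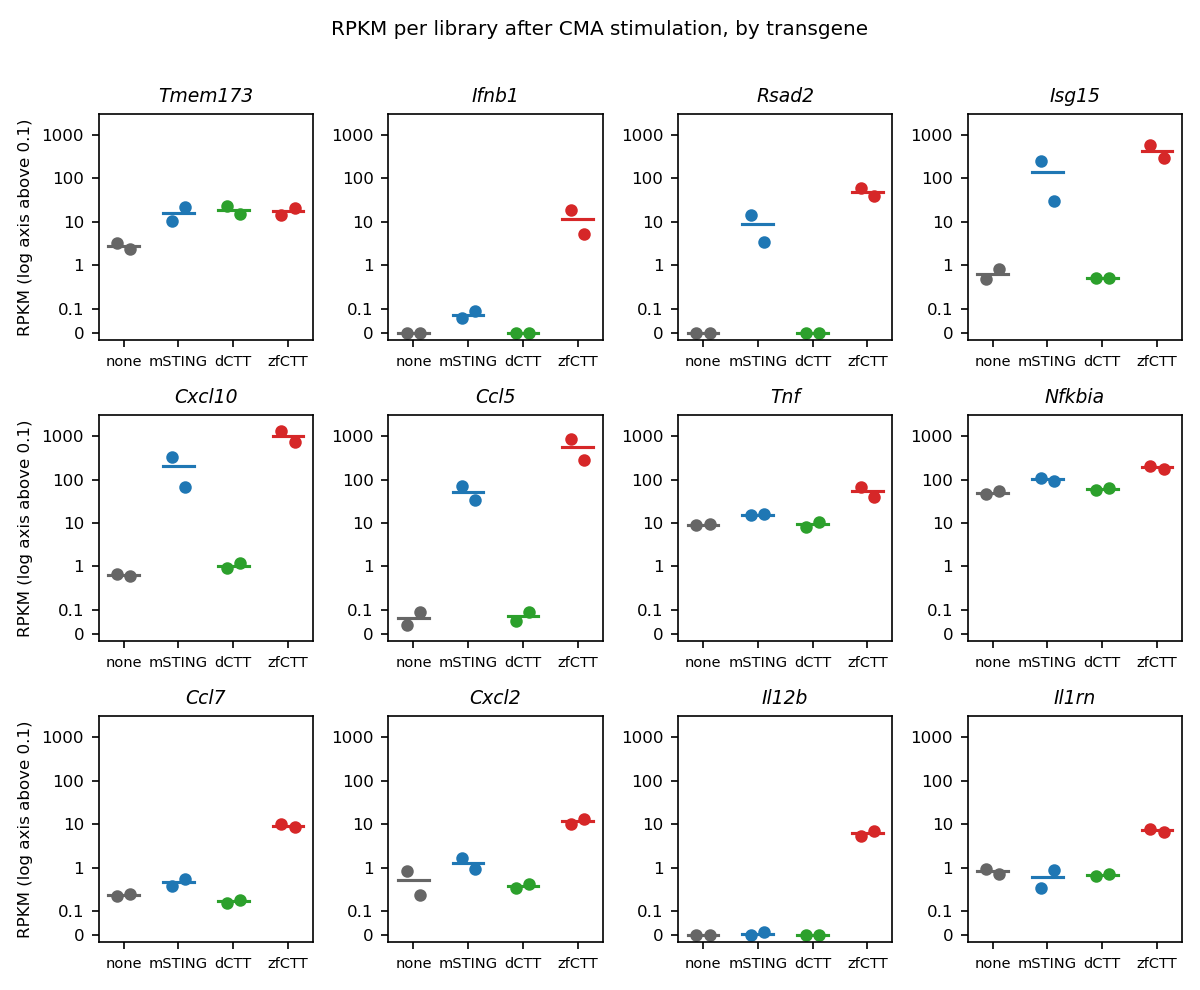
RPKM of 12 genes in each library after CMA, on an axis that is linear below 0.1 and logarithmic above it; points are libraries, bars are the means of the 2 libraries of a group, and none stands for the libraries without transgene. Cxcl10 lies at 68.9 RPKM or more in the 4 libraries with mSTING or zfCTT and at 1.19 or less in the 4 without transgene or with dCTT, while Il12b lies above 1 only in the 2 zfCTT libraries.

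The comparison of mSTING with no transgene addresses what the mouse protein adds to the response to CMA. Interferon-inducible transcripts were higher in both mSTING libraries, though not one gene passed the test. Cxcl10, a chemokine that draws in activated T cells, averaged 202 ± 188 RPKM (SD, n = 2) with mSTING and 0.635 ± 0.0299 without, a log2 difference of 6.55 ± 0.68 (limma, adjusted p = 0.131). Ccl5, another T cell chemokine, averaged 51.5 ± 25.2 against 0.0651 ± 0.0389 (5.54 ± 0.54, adjusted p = 0.117). Acod1, the enzyme that makes itaconate in activated macrophages, averaged 6.48 ± 1.42 against 0.215 ± 0.0317 (2.61 ± 0.20, adjusted p = 0.0752, the smallest of this comparison). Rsad2, which encodes the antiviral protein viperin, had 5537 and 1323 reads with mSTING and 0 in both libraries without, which makes it at least 565-fold higher (218 to 1313 with each library of the 2 groups left out). Ifit1, an RNA-binding antiviral protein, had 3212 and 509 reads against 0 and was at least 306-fold higher by the same floor of 3 reads per library (83.8 to 712). Ifnb1, the gene of interferon β (GRCm38 chromosome 4, 88522025 to 88522774, minus strand), had 4 and 6 reads with mSTING and 0 without, too few for a difference to be detectable at this depth.

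By list, all 43 tested interferon-stimulated genes had a positive difference with mSTING. Over all genes 0 passed, and 24 rose when adjusted over the list alone, with a median log2 fold change of 1.33, or 1.36 with the 4 members at 0 without transgene set at their bound. Among the examples, Rtp4 differed by 3.74 ± 0.41 (adjusted p over all genes 0.136) and Isg15, a ubiquitin-like modifier, by 5.76 ± 0.88 (0.498). Camera with its preset correlation placed this list above the other genes (adjusted p = 7.7e-37), a call that was lost at adjusted p = 0.325 with an estimated correlation. The 2 mSTING libraries differed in size of response: the median was 2.07 without mSTING replicate 2 and 0.70 without mSTING replicate 1. It was 2.98 with a pseudocount of 0.1, 2.51 with a mean RPKM of at least 5 and 3.47 by voom. In the interferon signalling list, 7 of 11 tested members rose when adjusted over the list alone and 0 over all genes (median 1.29, with adjusted p = 0.325 with an estimated correlation). The median was 0.69 without mSTING replicate 1 and 0.58 without the filter. Irf9, a subunit of the factor that carries interferon signals to the nucleus, was among the 7 at 1.92 ± 0.21.

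The NF-κB list, which holds target genes and feedback regulators, had 0 of 33 tested members past the threshold with mSTING by either count. Its median was 0.26 (camera adjusted p = 1.3e-05; adjusted p = 0.325 with an estimated correlation), or 0.17 without no_transgene replicate 1 or without the filter. Nfkbia, the gene of the NF-κB inhibitor IκBα, differed by 0.99 ± 0.19 and Tnf, an inflammatory cytokine, by 0.69 ± 0.27, each at adjusted p = 0.840. Among inflammatory cytokines 0 of 11 passed by either count. Their median was 0.28, or 0.05 without mSTING replicate 1, 0.55 without mSTING replicate 2, 0.04 without the filter and 0.45 by voom. The camera call on them was lost without no_transgene replicate 1 (median 0.26) or 2 (0.28) and at adjusted p = 0.325 with an estimated correlation. Of 12 chemokines, 0 passed over all genes and 2 rose when adjusted over the list alone (median 0.51; 0.33 without mSTING replicate 1 and 0.31 without no_transgene replicate 2; adjusted p = 0.325 with an estimated correlation). That median was 1.09 with a pseudocount of 0.1, 0.23 without the filter, 1.53 with a mean RPKM of at least 5, 1.15 by voom and 1.24 without either zfCTT replicate. Limma called 0 of 13475 genes in this comparison, with 467 at an unadjusted p under 0.05 against 674 expected by chance. Fewer small p-values than expected mean that the test leaned towards making no call. The 0 calls therefore do not show that mSTING and no_transgene are equal. Voom on the recovered reads also called 0. The count was 16 without mSTING replicate 2, 11 with a pseudocount of 0.1, 1 with 0.5, 12 without the filter on low values and 6 among protein-coding genes alone.

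Interferon and NF-κB genes in the dCTT libraries read at levels near those without transgene, and none of the differences passed the test. Cxcl10 averaged 1.05 ± 0.198 RPKM (SD, n = 2) with dCTT and 0.635 ± 0.0299 without transgene (log2 difference 0.32 ± 0.68). Isg15 averaged 0.504 ± 0.0073 against 0.644 ± 0.236 (−0.12 ± 0.88) and Tnf 9.40 ± 1.61 against 9.16 ± 0.415 (0.03 ± 0.27). Ifnb1, Rsad2, Ifit1 and Il12b had 0 reads in all 4 of these libraries. The limit that 0 allows, 3 reads, corresponds to a mean of 0.0476 RPKM for Ifnb1 in dCTT. Adjusted p was 1 for each gene named here that has a test. The medians were −0.01 over 43 interferon-stimulated genes, 0.05 over 33 NF-κB genes, 0 over 11 cytokines and −0.12 over 12 chemokines, and 0 members of these lists passed by either count. Mitochondrially encoded genes had a median of 0.38 and replication-dependent histone genes of 0.37. Camera placed both above the other genes (adjusted p = 5.4e-08 and 1.6e-09), a call lost at adjusted p = 0.825 with an estimated correlation. It was also lost without no_transgene replicate 2 for the former (0.16) and without no_transgene replicate 1 for the latter (0.14). The histone median was 0.62 without no_transgene replicate 2 and 0.17 without no_transgene replicate 1 and dCTT replicate 1 together. With mSTING over the same no_transgene libraries the histone median was 0.33, or 0.03 without no_transgene replicate 1 and 0.57 without replicate 2. Limma called 0 genes, with 36 at an unadjusted p under 0.05 against 674 expected by chance, and voom called 0. So few small p-values mean that the test leaned towards making no call here. The 0 calls therefore do not show that dCTT and no_transgene are equal.

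Set against mSTING, dCTT had lower levels of interferon-inducible transcripts. Cxcl10 differed by −6.23 ± 0.68 on the log2 scale (SE, n = 2 per group; limma, adjusted p = 0.164), Ccl5 by −5.52 ± 0.54 (0.164), Rtp4 by −3.72 ± 0.41 (0.164) and Acod1 by −2.39 ± 0.20 (0.130). For each of the 4, both dCTT libraries lay below both mSTING libraries. Rsad2, with 0 reads in dCTT, was at least 1090.3-fold higher with mSTING (420 to 2224 with each library of the 2 groups left out) and Ifit1 at least 591-fold (162 to 1206). All 43 interferon-stimulated genes had a negative difference, and 24 fell when adjusted over the list alone and 0 over all genes (median −1.35, or −1.49 with 4 members at their bound; −0.68 without mSTING replicate 1 and −2.07 without mSTING replicate 2). It was −2.94 with a pseudocount of 0.1, −2.51 with a mean RPKM of at least 5 and −3.50 by voom. Camera's call (adjusted p = 1.7e-54) was lost at adjusted p = 0.203 with an estimated correlation. Of the interferon signalling list 7 of 11 fell when adjusted over the list alone (median −1.38, with adjusted p = 0.203 with an estimated correlation). The median was −0.77 without mSTING replicate 1 and −0.45 without the filter. Of the chemokines 3 of 12 fell when adjusted over the list alone (median −0.62, with adjusted p = 0.203 with an estimated correlation). The chemokine median was −1.49 without either zfCTT replicate, when fewer members pass the filter, −1.37 with a pseudocount of 0.1, −0.32 without the filter, −1.76 with a mean RPKM of at least 5 and −1.66 by voom. The NF-κB list had 0 of 33 members past the threshold by either count (median −0.22; camera adjusted p = 1.3e-05, adjusted p = 0.267 with an estimated correlation). Limma called 0 genes, with 336 at an unadjusted p under 0.05 against 674 expected by chance, and voom 0. Here too the test leaned towards making no call, so 0 calls do not show that dCTT and mSTING are equal. The count was 10 without mSTING replicate 2, 3 with a pseudocount of 0.1, 14 without the filter and 7 among protein-coding genes.

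With zfCTT, macrophages held far more transcript of interferon-inducible genes and of NF-κB-linked cytokines and chemokines than without transgene. Cxcl10 (GRCm38 chromosome 5, 92346638 to 92348889, minus strand) rose to 1275 and 734 RPKM from 0.657 and 0.614 (log2 fold change 9.21 ± 0.68, SE, n = 2 per group; limma, adjusted p = 0.0101). Ccl5 rose to 840 and 279 (8.83 ± 0.54, adjusted p = 0.00443). Isg15 rose by 7.98 ± 0.88 (adjusted p = 0.0203), Oasl1 by 6.52 ± 0.56 (0.0130), Irf7, a transcription factor for interferon genes, by 5.83 ± 0.86 (0.0438) and Ccl4, a macrophage chemokine, by 5.86 ± 0.63 (0.0196). Ifnb1 averaged 11.9 ± 9.55 RPKM (SD), from 281 and 135 reads, and was at least 129.8-fold above the 0 reads of no_transgene (56.3 to 302 with each library of the 2 groups left out). Rsad2 was at least 3129.5-fold (1994 to 7275) and Ifit1 at least 1059-fold higher (674 to 2461). Among inflammatory genes, Tnf rose from 9.16 ± 0.415 to 53.1 ± 19.5 RPKM (2.36 ± 0.27, adjusted p = 0.0203) and Nfkbia from 50.1 ± 4.80 to 193 ± 23.3 (1.92 ± 0.19, 0.0196). Il12b, a subunit shared by the cytokines IL-12 and IL-23, was at least 174-fold higher (111 to 405), with 205 and 480 reads against 0.

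In the list of interferon-stimulated genes, 22 of 43 tested members rose over all genes and all 43 when adjusted over the list alone, with a median log2 fold change of 3.19 (3.22 with 4 members at their bound; 5.38 by voom and 4.98 with a pseudocount of 0.1). Of the interferon signalling list, 8 of 11 rose over all genes and 9 when adjusted over the list alone (median 2.73). NF-κB targets and feedback regulators rose in 8 of 33 over all genes and in 20 of 33 when adjusted over the list alone (median 1.39). Cd40, a co-stimulatory receptor, was at 3.72 ± 0.54, Traf1, a signalling adaptor, at 3.48 ± 0.54 and Nfkbie at 2.92 ± 0.41. Tnfaip3, the gene of the feedback regulator A20, was at −0.04 ± 0.22. Inflammatory cytokines rose in 6 of 11 and 10 of 11 by the same counts (median 2.10; 1.16 without zfCTT replicate 1 and 0.94 without the filter). They include Csf1, a macrophage growth factor, at 3.20 ± 0.32 and Il1rn, the natural antagonist of the IL-1 receptor, at 2.16 ± 0.21. Chemokines rose in 7 of 12 and 11 of 12 (median 3.17; 5.12 by voom). Among them were Ccl7 at 3.05 ± 0.16 (adjusted p = 0.00292) and Cxcl2, which attracts neutrophils, at 3.05 ± 0.26. The MHC class I presentation list had 0 of 21 past the threshold over all genes and 16 higher when adjusted over the list alone (median 1.22). Camera's calls on these 6 lists, at adjusted p from 2.0e-48 to 1.1e-13, did not hold with an estimated correlation. That gave adjusted p = 0.139 for interferon-stimulated genes, 0.125 for interferon signalling, 0.0691 for each of the NF-κB, cytokine and chemokine lists and 0.189 for MHC class I. Fry, which asks whether a list's genes move one way and makes no comparison with other genes, called all 6, at adjusted p = 0.0418 or less.

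**Figure D2:**
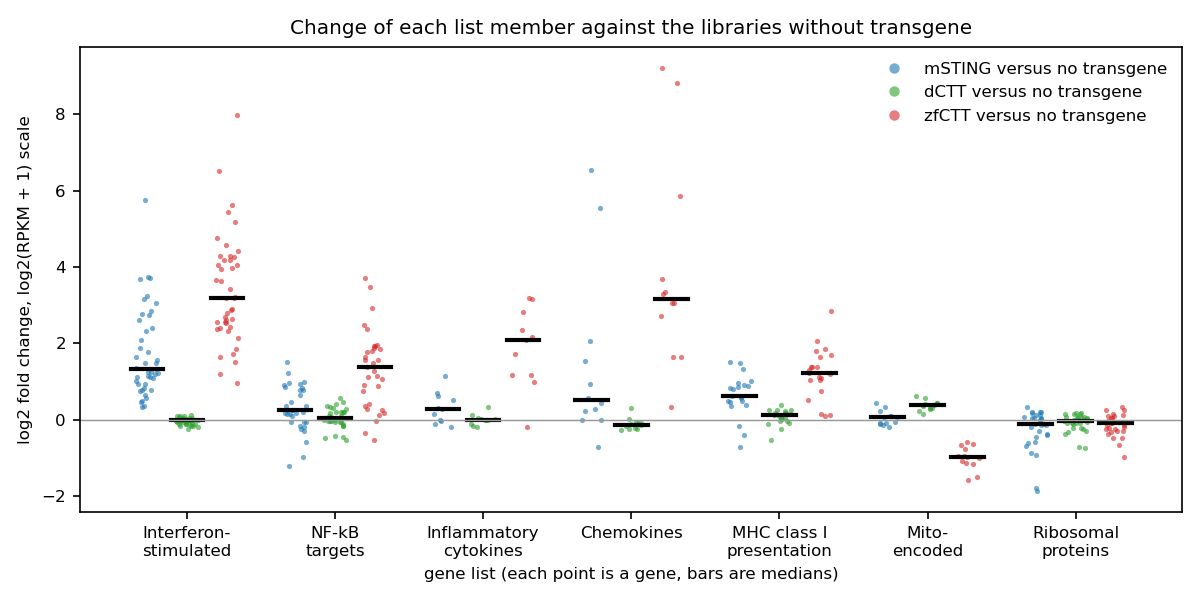
Log2 fold change over the libraries without transgene, on the log2(RPKM + 1) scale, of each tested member of 7 gene lists; each point is a gene, colours are the 3 transgenes and bars are list medians. The median of the interferon-stimulated genes is 3.19 with zfCTT, 1.33 with mSTING and −0.01 with dCTT, that of the NF-κB targets is 1.39, 0.26 and 0.05, and that of the ribosomal proteins lies between −0.11 and −0.04.

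Transcripts that fell with zfCTT included Cebpa, a transcription factor of myeloid differentiation, which read 24.9 and 42.8 RPKM without transgene and 3.06 and 6.50 with zfCTT (fell by 2.61 ± 0.39 on the log2 scale, SE, n = 2 per group; limma, adjusted p = 0.0452). Hes1, a Notch target, fell by 2.22 ± 0.27 (0.0244) and Tmem37 by 2.34 ± 0.26 (0.0203). Vsir, an immune checkpoint receptor, fell by 1.80 ± 0.25 (0.0374), Itgb5, an integrin subunit, by 1.66 ± 0.20 (0.0243) and C5ar2, a receptor for complement C5a, by 1.49 ± 0.23 (0.0454). The mitochondrially encoded genes were lower in all 13 of 13 members (median −0.98; −0.64 without no_transgene replicate 1), of which 2 fell over all genes and 4 when adjusted over the list alone. Camera's call at adjusted p = 6.1e-08 was lost at adjusted p = 0.148 with an estimated correlation. All genes of the mitochondrial chromosome together, not these 13 alone, took 0.0802% and 0.0826% of reads in the zfCTT libraries. In the other 6 libraries they took 0.143% to 0.221%. Actb and Gapdh, common reference transcripts, differed by 0.32 ± 0.17 and 0.04 ± 0.19, and 29 ribosomal protein genes had a median of −0.09 with 0 members past the threshold.

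Limma called 146 genes between zfCTT and no_transgene, 125 higher and 21 lower, with 1808 at an unadjusted p under 0.05. Of the 146, 125 are protein-coding. Acod1, at 54.3 and 43.5 RPKM against 0.192 and 0.237, had the smallest adjusted p (5.35 ± 0.20, 7.1e-04), and was past the threshold in 21 of 22 alternatives. Ccl5 was past it in 19 of 22, Cxcl10 in 18, Tnf and Nfkbia in 13 each, and Cebpa in 8. Both zfCTT libraries lay beyond both no_transgene libraries for all 146. The count rested on most of the libraries. It was 2 without no_transgene replicate 1, 8 without no_transgene replicate 2, 10 without dCTT replicate 1, 6 without dCTT replicate 2 and 49 without zfCTT replicate 2. It was 2 without zfCTT replicate 1, the library with the highest score on the first principal component. It was 0 without no_transgene replicate 1 and dCTT replicate 1 together, a fit left with 2 residual degrees of freedom. With the replicate number as a block it was 432, 298 higher and 134 lower. It was 48 by voom, 13 with library weights, 32 from the 4 libraries alone, 34 without the filter on low values, 64 with a mean RPKM of at least 5 and 379 among protein-coding genes alone.

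Compared with mSTING, zfCTT gave higher levels of cytokine and chemokine transcripts. Ccl7, a monocyte chemokine, rose from 0.453 ± 0.12 RPKM (SD, n = 2) with mSTING to 9.24 ± 0.841 with zfCTT (log2 difference 2.82 ± 0.16, SE; limma, adjusted p = 0.00975). Cxcl2 rose by 2.47 ± 0.26 (0.0442), Il1rn by 2.36 ± 0.21 (0.0306) and Acod1 by 2.74 ± 0.20 (0.0122). Il12b had 205 and 480 reads with zfCTT and 0 and 2 with mSTING (2.81 ± 0.18, adjusted p = 0.0113). Its difference was 5.86 with a pseudocount of 0.1, where the call was lost, and 9.93 by voom. Car2, carbonic anhydrase 2, read 313 and 175 RPKM with zfCTT and 5.24 and 7.76 with mSTING (rose by 4.99 ± 0.36, adjusted p = 0.0122). Cd274, the gene of the checkpoint ligand PD-L1, which was chosen after its values were seen, rose by 2.31 ± 0.22 (0.0332). H2-Eb1, an MHC class II chain, rose by 2.39 ± 0.23 (0.0332) and Ppic by 2.71 ± 0.28 (0.0437), and Dlx2, a homeobox factor, fell by 1.81 ± 0.19 (0.0437).

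Chemokines were higher with zfCTT than with mSTING in 12 of 12 tested members, of which 2 rose over all genes and 12 when adjusted over the list alone (median 2.43). Members that reach an RPKM of 1 only with zfCTT pass the filter, so such counts over tested members can lean towards zfCTT. Cytokines rose in 2 of 11 and 9 of 11 (median 1.67; 1.02 without zfCTT replicate 1 and 0.69 without the filter), and the NF-κB list in 0 of 33 and 13 of 33 (median 0.81). Nfkbia differed by 0.93 ± 0.19 (adjusted p = 0.224) and Tnf by 1.67 ± 0.27 (0.131). Camera's calls on these 3 lists were lost with an estimated correlation, at adjusted p = 0.104 for each. Interferon-stimulated genes rose in 0 of 43 over all genes and in 32 of 43 when adjusted over the list alone (median 1.56; 0.88 without mSTING replicate 2). That list had adjusted p = 0.270 with an estimated correlation and 0.0975 by fry. Cxcl10 differed by 2.66 ± 0.68 (0.344) and Irf9 by 0.14 ± 0.21 (0.790). The interferon signalling list rose in 0 and 7 of 11 (median 1.60; 0.80 without mSTING replicate 2, 2.40 without mSTING replicate 1 and 0.67 without the filter; adjusted p = 0.270 with an estimated correlation). Dendritic cell markers rose in 1 of 5 over all genes, H2-Eb1, and in 4 of 5 when adjusted over the list alone (median 1.88, with adjusted p = 0.104 with an estimated correlation). Their median was 3.60 by voom, 3.15 with a pseudocount of 0.1 and 0.10 without the filter. The 4 are the MHC class II genes H2-Eb1, H2-Aa and H2-Ab1 with the invariant chain Cd74, the last 3 named after their values were seen. Over no_transgene, all 5 markers were higher with zfCTT (median 1.07) and all 5 lower with mSTING (median −0.81), so the difference between the 2 holds both. With zfCTT, 1 of 5 rose over all genes, H2-Eb1 at 1.48 ± 0.23 (adjusted p = 0.0459), and 3 when adjusted over the list alone. With mSTING 0 fell over all genes and 2 when adjusted over the list alone. With an estimated correlation the list had adjusted p = 0.125 with zfCTT and 0.325 with mSTING. Camera's call for mSTING (adjusted p = 0.0134) was lost without no_transgene replicate 2 (−0.59) or mSTING replicate 2 (−0.91). The median with mSTING was −1.70 with a pseudocount of 0.1, −0.04 without the filter and −2.13 by voom, and that with zfCTT 0.08 without the filter and 0.67 without zfCTT replicate 2. Mitochondrially encoded genes fell in 0 of 13 over all genes and in 8 when adjusted over the list alone (median −0.97; adjusted p = 0.160 with an estimated correlation).

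**Figure D3:**
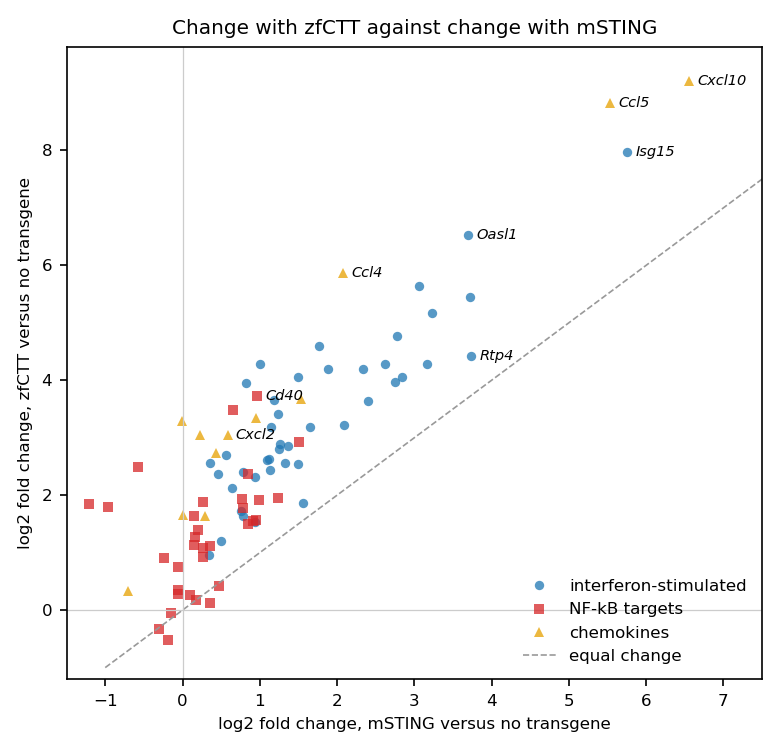
Log2 fold change over the libraries without transgene with zfCTT (vertical axis) against that with mSTING (horizontal axis), on the log2(RPKM + 1) scale, for each tested interferon-stimulated gene (circles), NF-κB target (squares) and chemokine (triangles); the dashed line marks equal change. All 43 interferon-stimulated genes and all 12 chemokines lie above the line, with Cxcl10 at 9.21 against 6.55 and Ccl4 at 5.86 against 2.08.

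In total limma called 16 genes between zfCTT and mSTING, 15 higher and 1 lower, with 1476 at an unadjusted p under 0.05. The calls rested on the libraries in the fit. The count was 5 without either no_transgene replicate, 0 without any 1 of the mSTING, dCTT or zfCTT libraries and 0 with a pseudocount of 0.1 or with the 4 libraries alone. It was 2 with a mean RPKM of at least 5 and 0 without no_transgene replicate 1 and dCTT replicate 1 together. With the replicate number as a block it was 44, 38 higher and 6 lower. It was 8 by voom, 29 without the filter on low values (14 higher and 15 lower) and 65 among protein-coding genes alone. Acod1 and Car2 were past the threshold in 13 of 22 alternatives each, Ccl7 and Il12b in 12 of 19, Cxcl2 in 7 of 21 and H2-Eb1 in 8 of 21.

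Set against dCTT, zfCTT libraries held more transcript of interferon-inducible genes, cytokines and chemokines. Cxcl10 rose by 8.89 ± 0.68 on the log2 scale (SE, n = 2 per group; limma, adjusted p = 0.0109), Ccl5 by 8.82 ± 0.54 (0.00554), Ccl4 by 6.10 ± 0.63 (0.0193) and Tnf by 2.34 ± 0.27 (0.0232). Ifnb1 was at least 251-fold higher (109 to 511 with each library of the 2 groups left out). Cebpa fell by 2.69 ± 0.39 (0.0415), Hes1 by 2.25 ± 0.27 (0.0248) and the mitochondrial transcripts mt-Cytb by 1.97 ± 0.29 (0.0428) and mt-Atp8 by 1.65 ± 0.21 (0.0267). Of these, Cebpa was past the threshold in 11 of 22 alternatives. Of 43 interferon-stimulated genes 22 rose over all genes and 43 when adjusted over the list alone (median 3.19, 3.53 with 4 members at their bound, 5.54 by voom, 4.96 with a pseudocount of 0.1). By the same counts, the NF-κB list had 3 and 21 of 33 (median 1.17). There were 6 and 10 of 11 for cytokines (1.96; 1.26 without zfCTT replicate 1 and 0.79 without the filter) and 7 and 11 of 12 for chemokines (3.32; 5.57 by voom and 2.16 without the filter). Mitochondrially encoded genes fell in 3 of 13 and 12 of 13 (median −1.40). With an estimated correlation these 5 lists had adjusted p = 0.155, 0.0769, 0.0769, 0.0769 and 0.138 in that order. Limma called 146 genes, 123 higher and 23 lower, with 1709 at an unadjusted p under 0.05. Voom called 157. The count was 26 without no_transgene replicate 1, 19 without no_transgene replicate 2, 1 without either dCTT replicate, 2 without zfCTT replicate 1, 83 without zfCTT replicate 2 and 0 without no_transgene replicate 1 and dCTT replicate 1 together. With the replicate number as a block it was 409, 284 higher and 125 lower. It was 65 from the 4 libraries alone, 28 without the filter on low values, 61 with a mean RPKM of at least 5 and 351 among protein-coding genes alone.

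Comparisons that share libraries share their chance values, so each overlap is given beside a simulation of the same design without change (50 draws). All 8 libraries, the shared ones included, were drawn anew from the gene means with independent noise. Deviations of the real shared libraries, and shifts common to libraries of different groups, are therefore not in the simulated values. Between zfCTT and mSTING, each over no_transgene, log2 fold changes across 13475 genes had r = 0.57 against 0.50 simulated and a covariance of 0.149 against 0.0780, a difference of 0.0712. They shared 0 calls because mSTING had 0. Between zfCTT and dCTT, each over no_transgene, the covariance was 0.0310 against 0.0777 (r = 0.23 against 0.50), and between mSTING and dCTT 0.0591 against 0.0777 (r = 0.58 against 0.50). The zfCTT comparisons with no_transgene and dCTT, which share the zfCTT libraries, had 112 genes called higher and 17 lower in both, Cxcl10 and Cebpa among them, where independent lists would share 1.14 and 0.0358 and the simulation gave 0 and 0.04. The zfCTT comparisons with no_transgene and mSTING had r = 0.68 against 0.50 simulated and a covariance of 0.198 against 0.0771, with 15 genes called higher in both, where independent lists would share 0.139, and 0 called lower. The shared groups were not split, since each part would hold 1 library, so part of each excess may come from them. Simulated groups without change and with independent noise have few calls to share, so their counts near 0 were set by the design. Comparisons that hold the same zfCTT libraries are likely to share calls. The counts of shared calls are therefore no evidence of a shared response.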

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

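All the tests of explanations in this part were chosen only after the result was seen, and the measures used for GC content and for a scaled response were also changed after their first results. The former had asked whether a median kept 0.5 of its size, and the 3 medians kept 1.01, 0.97 and 0.73 of it. It now asks whether the median lies more than 1 SD of its members from 0, with the same reading in all 3. The latter had asked only for an excess above 0 in each fit, which argued against the explanation, and under the 1 SD measure it no longer does.

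In its change over no_transgene, zfCTT differed from mSTING and from dCTT by tests of the difference itself. Limma called 16 genes between zfCTT and mSTING and 146 between zfCTT and dCTT, counts that rested on the libraries in the fit. Between dCTT and mSTING it called 0. In lists, the median log2 difference between zfCTT and mSTING was 0.81 for NF-κB targets and feedback regulators, 1.67 for inflammatory cytokines, 2.43 for chemokines, 1.88 for dendritic cell markers and −0.97 for mitochondrially encoded genes. Each of these 5 was past the threshold by camera with its preset correlation and by fry, which was the rule for listing them here and adds no support. None was past it with an estimated correlation (adjusted p = 0.104 for the first 4 and 0.160 for the last).

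Tests ran on the 56 tested members of the NF-κB, cytokine and chemokine lists that are not in the interferon lists. Their median difference between zfCTT and mSTING was 1.21 (SD 1.06 over members). They include Cxcl10 and Ccl5, described above as interferon-inducible, so the set is not an NF-κB response separate from interferon. Only 47 members passed the filter with either zfCTT replicate left out. A GC trend as the whole cause is argued against, though narrowly, since the median was 1.17 (SD 1.02) with the trend removed and 51 members stayed positive. A single response that zfCTT only turns up cannot be told apart from the pattern: with the mSTING changes multiplied by 2.40, the ratio of the interferon-stimulated medians, the median excess was 0.61 (SD 1.74) with 42 of 56 members above 0, and without mSTING replicate 1 the ratio was 4.55 and 30 members were above 0. Nor is a larger amount of transgene transcript excluded, which cannot be told apart because the Tmem173 difference of 0.14 has a 95% interval from −0.77 to 1.06. Differences between dishes and the difference between the transgenes themselves also stay open, untested.

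The 2 mSTING libraries differed in the interferon-stimulated genes, 42 of 43 of which were higher in replicate 1 (median log2 difference 1.39, SD 0.63), and the count and medians of the mSTING comparisons moved with this library. Less transgene transcript in replicate 2 is argued against, since Tmem173 went the other way, with a log2 ratio of replicate 1 over replicate 2 of −1.06 (2567 and 5352 reads, counting SE 0.03). RNA of zfCTT in mSTING replicate 1 is argued against by 21 NF-κB, cytokine and chemokine genes, with the interferon-inducible Cxcl10 and Ccl5 among them. These 21 imply a median share of 6.94% (quartiles −1.76% and 16.4%) where 22 interferon-stimulated genes imply 45.1% (25.6% and 52.6%). GC content is argued against by a median of 1.41 (SD 0.64) with the trend removed. Stimulation, cell state or handling that differed between the dishes could give such a gap and was not tested, and the design gives no biological explanation for a gap within a group.

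Mitochondrially encoded transcripts were lower with zfCTT than without transgene (median log2 fold change −0.98, SD 0.30 over 13 members). These genes have a median GC content of 37.1% against 50.8% of all tested genes, but with the GC trend removed the median was −0.72 (SD 0.27), which argues against that trend as the whole cause while leaving it a part. Reads taken up by induced genes are argued against by the median of all tested genes, −0.042. RNA quality, poly(A) selection that differed between preparations and an effect of zfCTT on mitochondria may each lie behind the rest and were not tested.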

How the results depend on the processing

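The fits by voom, without no_transgene replicate 1 and dCTT replicate 1 together, on protein-coding genes alone and with the GC trend removed were chosen only after the results were seen. For the genes of the text, 1062 values under settings fixed in advance kept direction and side of the threshold, 364 lost the call, 22 gained it and 9 changed sign; under the added settings these were 242, 71, 17 and 2. By result, 6 of 83 gene results changed sign in at least 1 alternative, with 0 of the 47 called ones among them. Of 58 list medians 13 did, with 1 of the 42 called by camera. Among results of the same fits that the text does not report, 43 of 335 genes and 45 of 86 medians changed sign, 0 of them called. The counts of calls moved more. For mSTING against no_transgene limma's 0 calls became 11 and 1 with pseudocounts of 0.1 and 0.5, 12 without the filter, 6 among protein-coding genes, and 0 to 16 with each library left out. The 0 for dCTT against no_transgene stayed 0 in all alternatives (36 at an unadjusted p under 0.05 against 674 expected by chance, voom 0). The 146 for zfCTT against no_transgene became 34 without the filter, 64 with a mean RPKM of at least 5, 32 in the 4 libraries alone, 13 with library weights, 48 by voom, 379 among protein-coding genes, 0 without the 2 libraries together, and 2 to 144 with each left out. The 16 for zfCTT against mSTING became 0 with a pseudocount of 0.1, 29 without the filter, 2 with a mean RPKM of at least 5, 0 in the 4 libraries alone, 8 by voom, 65 among protein-coding genes, 0 without the 2 libraries, and 0 to 5 with each left out. For dCTT against mSTING 0 became 3 with a pseudocount of 0.1, 14 without the filter, 7 among protein-coding genes, and 0 to 10 with each left out. The 146 for zfCTT against dCTT became 28 without the filter, 61 with a mean RPKM of at least 5, 65 in the 4 libraries alone, 351 among protein-coding genes, 0 without the 2 libraries, and 1 to 148 with each left out. The genes called for both mSTING and zfCTT over no_transgene, 0, became 11 and 1 with the 2 pseudocounts, 1 without the filter, 6 among protein-coding genes, and 0 to 14 with each left out. Fits with fewer libraries have fewer residual degrees of freedom, which can lower such counts by construction. That loss is not the whole account. For zfCTT against no_transgene the count held nearly as it was without either mSTING replicate and dropped steeply without either dCTT replicate, at the same loss. Without either mSTING replicate only the size of the list held. Part of the genes called differed from those of the main fit, and fewer of them were lower. For the other settings the cause was not tested.

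The replicate numbers were used as a block only as an alternative, since nothing in the labels says what they share. Deviations of same-numbered libraries correlated across genes at 0.03 to 0.76, with 2 of 6 pairs under 0.1. The others were 0.76 for no_transgene with dCTT, 0.43 for no_transgene with zfCTT, 0.40 for dCTT with zfCTT and 0.26 for mSTING with zfCTT. A shift shared by same-numbered libraries would enter the error of the main fit, which has no block. With the block, the counts were 432 for zfCTT against no_transgene, 44 against mSTING and 409 against dCTT, and 0 in the other 3 comparisons, and Tmem173 with zfCTT passed at 2.25 (adjusted p = 0.0452). It also passed among protein-coding genes (2.31) and with the GC trend removed (2.25), and it ran from 2.0 to 2.51 with each library left out, while mSTING ran from 1.61 to 2.61 and dCTT from 2.07 to 2.64.

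With an estimated correlation camera called neither list: adjusted p for interferon-stimulated genes was 0.325 for mSTING against no_transgene, 0.139 for zfCTT against no_transgene and 0.270 for zfCTT against mSTING, and for the NF-κB list 0.325, 0.0691 and 0.104. Fry gave 0.276 for both lists with mSTING and 0.0975 for interferon-stimulated genes between zfCTT and mSTING. With each library left out, the interferon-stimulated median ran from 0.70 to 2.07 for mSTING, 2.72 to 3.81 for zfCTT and 0.88 to 2.28 between them, and the NF-κB median from 0.17 to 0.36, 0.98 to 1.79 and 0.66 to 1.02. The signs that changed follow. With a mean RPKM of at least 5, MAPK feedback genes with zfCTT went from 0.47 to −0.25, p53 targets with zfCTT from 0.05 to −0.22 and STING and nucleic acid sensing genes between zfCTT and dCTT from 0.16 to −0.18. In the same setting, cholesterol genes with mSTING went from −0.05 to 0.19, cell cycle genes with dCTT from −0.08 to 0.0069 and interferon-stimulated genes with dCTT from −0.01 to 0.0027. Without the filter p53 targets with zfCTT were at −0.0036 and dendritic cell markers with dCTT at −0.016 (from 0.04), and the latter at −0.013 with a pseudocount of 0.1. Cell cycle genes with zfCTT went from −0.01 to 0.013 with median-of-ratios scaling, 0.020 with quantile normalization, 0.046 among protein-coding genes and 0.23 without the 2 libraries. Cholesterol genes with mSTING were at 0.044 with quantile normalization and Tnfaip3 with zfCTT at 0.017 among protein-coding genes (from −0.04). With the GC trend removed, cholesterol genes with mSTING were at 0.080, ribosomal protein genes with mSTING at 0.015 (from −0.11), interferon-stimulated genes with dCTT at 0.072 and dendritic cell markers with dCTT at −0.070. Without the 2 libraries together, immediate early genes with dCTT were at −0.016, cell cycle genes with dCTT at 0.015, unfolded protein response genes with zfCTT at 0.029, ribosomal protein genes with zfCTT at 0.035 and Tmem173 between dCTT and mSTING at −0.038. With each library left out, immediate early genes with dCTT ran from −0.22 to 0.31, cell cycle genes with dCTT from −0.35 to 0.14 and with zfCTT from −0.15 to 0.23, and cholesterol genes with mSTING from −0.25 to 0.16. Dendritic cell markers with dCTT ran from −0.50 to 0.25, ribosomal protein genes from −0.10 to 0.059 with dCTT and −0.22 to 0.035 with zfCTT, and unfolded protein response genes with zfCTT from −0.11 to 0.057. Among genes, Tmem173 over mSTING ran from −0.35 to 0.64 with zfCTT and −0.25 to 0.74 with dCTT, Tnf with dCTT from −0.13 to 0.19 and Isg15 with dCTT from −0.27 to 0.026. Tnfaip3 with zfCTT ran from −0.23 to 0.14 and Gapdh from −0.019 to 0.10. The cause of these changes was not tested. Depth limits the low genes most in zfCTT, at 20.1 and 34.8 M reads, and Ifnb1 with mSTING rests on 4 and 6 reads.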

Other observations

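In this part the genes said to be chosen after their values were seen, and their grouping, were picked only after the result was seen; the lists and their tests were planned.

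Genes that restrain MAP kinase signalling or respond to it differed in both directions with zfCTT, though none passed over all genes. Of 13 tested members of the MAPK feedback list, 0 passed over all genes, while 5 rose and 4 fell when adjusted over the list alone, and the list as a whole had a median of 0.47, or −0.25 with a mean RPKM of at least 5, 0.17 without no_transgene replicate 1, 0.13 without zfCTT replicate 1 and 0.29 without the filter (camera adjusted p = 0.548; fry in either direction, adjusted p = 0.00234). Dusp6, an ERK phosphatase, averaged 26.1 ± 3.73 RPKM (SD, n = 2) without transgene and 8.30 ± 3.47 with zfCTT (log2 difference −1.59 ± 0.29, SE; limma, adjusted p over all genes 0.0638). The transcription factors Etv4 and Etv5, which respond to ERK signalling, differed by −1.37 ± 0.24 (0.0571) and −1.25 ± 0.22 (0.0606). Dusp1, chosen after its values were seen, differed by 1.24 ± 0.26 (0.0925). In the immediate early and AP-1 list 1 of 21 rose over all genes, Csrnp1 at 2.79 ± 0.32 (adjusted p = 0.0203), and 10 rose and 3 fell when adjusted over the list alone (median 0.74; camera adjusted p = 0.00164, adjusted p = 0.440 with an estimated correlation). Camera's call was lost without no_transgene replicate 1, at a median of 0.52.

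Several other lists had single members past the threshold between zfCTT and no_transgene. Trex1, the DNA exonuclease that removes STING-activating DNA, rose from 20.9 ± 3.54 to 206 ± 11.2 RPKM (SD, n = 2; 3.25 ± 0.38, SE; limma, adjusted p = 0.0230), the 1 of 18 STING and nucleic acid sensing genes to rise over all genes. In that list 7 rose when adjusted over the list alone (median 0.32, with camera adjusted p = 0.00481 and adjusted p = 0.125 with an estimated correlation). Camera made no call with a mean RPKM of at least 5, at a median of 0.34, and the median was 0.49 without zfCTT replicate 2. Among 14 p53 targets, Mdm2, which targets p53 for degradation, rose by 1.32 ± 0.21 and Sesn1, a stress-response gene, fell by 1.26 ± 0.20, each at adjusted p = 0.0459, while the list had a median of 0.05, or −0.22 with a mean RPKM of at least 5. With each library left out the p53 median ran from 0.05 to 0.19. Daxx rose by 2.26 ± 0.35 (0.0459) among 16 cell death genes, of which 4 rose when adjusted over the list alone (median 0.07; camera adjusted p = 0.0136, adjusted p = 0.148 with an estimated correlation). That call was lost without no_transgene replicate 1 (median 0.34) or zfCTT replicate 2 (0.17). Of 23 macrophage identity genes 18 had a negative difference and 1, Cebpa, fell (median −0.67; −0.37 without zfCTT replicate 1 and −0.41 without the filter; camera adjusted p = 0.00113, adjusted p = 0.229 with an estimated correlation). That list was also lower with mSTING over no_transgene, at a median of −0.36 (−0.24 without no_transgene replicate 2). Both comparisons use the same no_transgene libraries, so they cannot tell whether the lean is particular to zfCTT. Cholesterol synthesis genes had a median of 0.39 with 0 of 20 past the threshold by either count (camera adjusted p = 2.5e-04, adjusted p = 0.247 with an estimated correlation). It was 0.63 with a mean RPKM of at least 5. Cell cycle genes had a median of −0.01 and unfolded protein response genes of −0.11, with 0 members past the threshold. Both medians changed sign without no_transgene replicate 1 or without zfCTT replicate 2.

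Markers of other cell types were mostly under the filter: 0 neutrophil and 0 mast cell markers, 1 fibroblast marker, 2 lymphocyte markers and 5 of 13 dendritic cell markers were tested. The dendritic cell markers had a median of 0.04 with dCTT over no_transgene, with 0 past the threshold by either count. Il1b read 3.30 and 0.241 RPKM in the zfCTT libraries and 0.454 or less in the other 6, a wide gap between the 2 zfCTT libraries. Il6 read 0.123 or less in all 8 libraries and Cxcl1 was at 0 in all 8. No_transgene replicate 1 differed from replicate 2 along GC content, with a Spearman correlation of −0.55 across 9449 protein-coding genes against 0.06, −0.06 and −0.25 in the mSTING, dCTT and zfCTT pairs; genes are not independent replicates.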
